A study of Oryza sativa with 8 samples.

How the data were processed

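The libraries were made from total RNA of field-grown rice leaves and sequenced as paired-end reads on an Illumina instrument, per the labels. The deposited table holds raw read counts per gene, as whole numbers made by the authors, with 1 column for each of the 8 libraries. Per the submitters' processing notes, the work used FastQC, Trim Galore, STAR 2.5.3a, DESeq2 and the rice genome build IRGSP-1.0, with no role or order given for them. The RNA selection, the counter, its strand setting and the annotation release are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense genes therefore carry an unknown error from read assignment, and the Rubisco small subunit and antenna families belong to the multigene families this concerns.

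Samples were grouped by their titles into WT replicates 1 to 4 and mEmBP-OE-4 replicates 1 to 4. The table has 36850 rows, of which 7687 had no count in any library. Rows with identifiers of other kinds than Os locus IDs numbered 1183, took 0.0193% to 0.0393% of each library's counts and were kept. Organelle genes were not told apart by name and are not analysed here as a class. No row is known here for the maize transgene, so its own expression was not analysed here.

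The files pair no locus ID with a gene name. The gene table for assembly ASM3414082v1 matched 1 of the row IDs, so no names could be taken from it, its coordinates were not used, and at most 4 IDs are printed. The tests, the named-gene rule, the alternative settings and 23 gene lists were fixed before the data were examined. Each list joined a search of product names with locus IDs recalled from memory. Without product names the searches returned nothing, so 17 lists held loci (142 written, 141 of them in the table, 130 tested) and 12 reached the 5 tested loci set as the minimum for a set test. The heat shock, bZIP, epidermis, cytosolic ribosome, plastid ribosome and redox lists had no loci and gave no result. List membership thus rests on recalled IDs and neither on the table nor on the reference. As a check of level, 12 of 14 antenna, 14 of 15 photosystem core, 14 of 17 Calvin-Benson, 7 of 10 photorespiration and 3 of 5 electron transport loci lay in the top 1% of tested genes by abundance. The planned product-family test and the parts of the named-gene rule that need a gene name were not run for the same reason. The remaining part, up to 2 called members of lowest p from each list, was limited to the 2 higher and 2 lower loci of lowest p over all lists.

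Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 20690 genes, and scaled by TMM. Groups were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, computed from the deposited counts on TMM-scaled library sizes. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 12 lists. Beside it stood camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes. Shares of counts were compared by exact permutation tests over all ways to choose 4 of the 8 libraries, for which 0.0286 is the smallest two-sided p. Calls were also followed along the locus order, taken from the numbering of the locus IDs and not from positions, in windows of 25 consecutive tested loci against 1000 shuffles.

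Replicate pairs within a group differed by far more than sampling noise (chi-square per degree of freedom 6.20 to 110), so all 8 libraries were counted. The labels number the replicates 1 to 4 in both groups without saying what a number shares. Deviations from the group means correlated between same-numbered libraries at 0.641, 0.347, 0.189 and 0.104. A different matching of the numbers had a higher mean correlation, 0.347 against 0.320, so it stays open whether the numbers pair the samples. The fit with the replicate number as a block is reported where it changes a result.

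The scaling and gene test, without the filter, were tried on simulated counts for 20690 genes with the means and library sizes of these samples. The test called 6.78% of 59 genes changed 1.5-fold, 47.9% of 73 changed 2-fold and 82.4% of 68 changed 4-fold, and 10 of 20490 unchanged genes. Genes were drawn independently there, and far fewer were changed than the 39.2% called in the data. These rates therefore need not hold for the real comparison. Libraries held 35627524 to 50800180 counts, and in this simulation small changes were the ones most often missed. Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios and upper-quartile factors, library totals alone, no filter, a filter of at least 5 CPM in 4 libraries, the replicate block, removal of the 50 most abundant genes, and leaving out each library in turn. Alternatives added after the data were seen were the block and library totals each with an estimated correlation, library totals after removal of the 50 most abundant genes, the pooled photosynthesis loci, both replicate 1 libraries left out together, and locus-order windows of changes over 8-fold.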

Results

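Leaf transcripts were measured by RNA sequencing in field-grown rice (Oryza sativa) at early heading. The leaf sampled was the second from the top of the plant, taken in mid-morning. WT was compared with mEmBP-OE-4, a rice line that overexpresses mEmBP-1a, a bZIP transcription factor from maize, with 4 libraries in each group. Total counts ranged from 35627524 in WT replicate 3 to 50800180 in mEmBP-OE-4 replicate 4. The mean was 40.7 ± 5.03 M counts in WT and 43.8 ± 5.59 M counts in mEmBP-OE-4 (SD, n = 4, two-sided exact permutation p = 0.429). The first principal component of log2 CPM held 66.8% of the variance and separated the groups, and the next held 16.5%. Across genes, libraries correlated at r = 0.958 to 0.993 within WT, 0.954 to 0.982 within mEmBP-OE-4 and 0.873 to 0.908 between the groups.

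**Figure D1:**
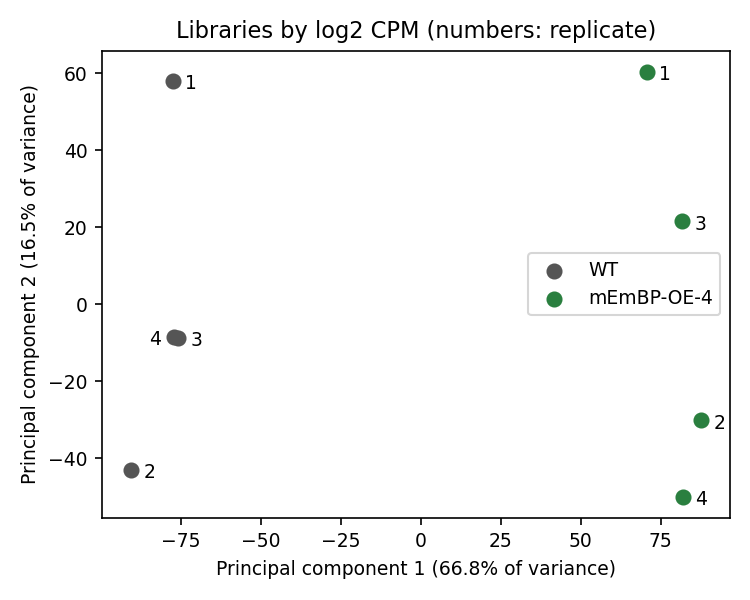
Libraries on the first 2 principal components of log2 CPM, with the percent of variance on each axis, points coloured by group and numbered by replicate. The WT libraries lie between -90.7 and -76.0 on the first component and the mEmBP-OE-4 libraries between 70.6 and 87.6, while replicate 1 of both groups lies highest on the other component (58.1 and 60.4).

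The comparison asked which leaf transcripts differ in the overexpression line, and in particular how those of photosynthesis stand. Transcripts of the photosynthetic apparatus were higher in mEmBP-OE-4 than in WT. Of 51 tested loci on the lists for antenna proteins, photosystem cores, electron transport and the Calvin-Benson cycle, 42 rose, each by at least 1.5-fold, 1 fell and 8 did not pass the test, with a median log2 fold change of 1.08. Together these loci took 32.5% ± 2.92 of the counts in mEmBP-OE-4 and 25.6% ± 1.98 in WT (SD, n = 4, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). On the chlorophyll synthesis list 8 of 12 loci rose and 1 fell, and on the photorespiration list 4 of 10 rose and none fell. Of 6 senescence loci 2 fell and 1 rose, and the WRKY locus fell. Pooling the 4 photosynthesis lists was decided after the data were seen. Of the pooled loci 82.4% rose, against 20.1% of all tested genes (two-sided Fisher's exact p = 1.92e-21, in which genes are not independent). The genes compared were not matched for abundance, and most pooled loci were among the most abundant genes. None of the 4 lists was called by camera with an estimated correlation (adjusted p = 0.356 for each).

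Across the leaf transcriptome, 8109 of 20690 tested genes changed (39.2%) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4155 of them higher and 3954 lower. At least 1.5-fold changes numbered 6361, with 3268 genes higher and 3093 lower, and 625 genes changed over 8-fold, 354 higher and 271 lower. The groups did not overlap in 38.5% of tested genes, where chance gives 2.86%. The split of directions depended on scaling. With library totals alone the median log2 fold change of all genes moved from 0.00 to -0.47, and 1752 genes were called higher and 8912 lower, so 16.4% of calls were higher in place of 51.2%. Against that lower median the photosynthesis loci still had a median of 0.59, with 36 higher and 2 lower. A filter of at least 5 CPM in 4 libraries left 5220 calls. Nothing in the labels says whether the replicates are separate plants. The p-values set the difference between groups against the spread between these libraries, which may be partly technical.

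Among loci listed for the light-harvesting antenna, the proteins that bind chlorophyll and pass on excitation energy, 11 of 14 rose and none fell, and 12 rose when adjusted over the list alone. The number was 6 without WT replicate 1, 2 or 4 or mEmBP-OE-4 replicate 4, and with library totals alone 7 rose and 1 fell. Os01g0720500, on chromosome 1 by its ID, went from 738 ± 131 to 4565 ± 1148 CPM (SD, n = 4), a log2 fold change of 2.63 (SE 0.24) with adjusted p = 6.94e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median of the list was 0.83, and 0.33 with library totals alone. Of the photosystem core loci, nuclear genes for subunits of photosystems I and II, 14 of 15 rose and 1 fell, both over all genes and adjusted over the list alone. The median was 1.04 (0.54 with library totals alone), and the mean of 0.60 was drawn down by the locus that fell, at -6.26.

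The electron transport list was meant for carriers of electrons from the photosystems to NADP and for the plastid ATP synthase. Whether any of its 5 recalled loci belongs to the ATP synthase was not checked. Of the 5 loci, 4 rose over all genes and 5 when adjusted over the list alone, with a median of 1.44 (0.92 with library totals alone). The lowest of them averaged only 3.55 CPM in WT and 8.03 CPM in mEmBP-OE-4. The next lowest, among the 4 that rose, averaged 4.49 CPM in WT and 12.3 CPM in mEmBP-OE-4. Of 17 Calvin-Benson loci, the enzymes of carbon fixation with the Rubisco small subunit and activase, 13 rose by either adjustment, none fell and 4 did not pass, with a median of 1.16 (0.67 with library totals alone). Photorespiration loci, which recycle the product of Rubisco's oxygenation, rose in 4 of 10 cases over all genes and 6 when adjusted over the list alone, with a median of 0.74. That number became 7 with the replicate block, with DESeq2 and without mEmBP-OE-4 replicate 1, and with library totals alone 3 rose, 1 fell and the median was 0.23. Of 12 chlorophyll synthesis loci, 8 rose and 1 fell over all genes, 9 and 1 when adjusted over the list alone, with a median of 0.62, and with library totals alone 6 rose, 2 fell and the median was 0.12.

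**Figure D2:**
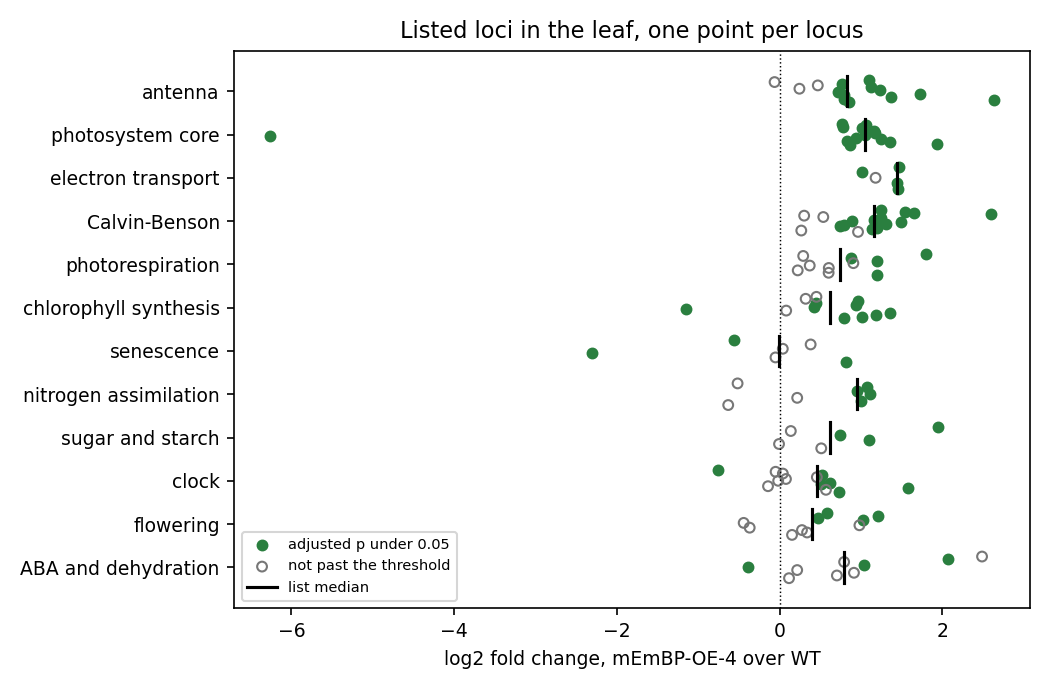
Log2 fold change of mEmBP-OE-4 over WT for each listed locus, by list, with filled points for loci past an adjusted p of 0.05, open points for the others and a bar at each list's median. Medians of the photosynthesis lists lie between 0.83 (antenna) and 1.44 (electron transport), and 1 photosystem core locus lies at -6.26; with library totals alone the clock and flowering medians fall below 0.

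Camera with Benjamini-Hochberg adjustment called 6 of the 12 testable lists, all of them upward against the other tested genes. The adjusted p was 3.00e-06 for Calvin-Benson, 5.30e-05 for photosystem core, 9.19e-05 for antenna, 0.00224 for photorespiration, 0.00508 for chlorophyll synthesis and 0.0142 for electron transport. None of the 6 calls held with an estimated correlation in camera, where each had an adjusted p of 0.356. Of the 35 ways to divide the 8 libraries into 4 and 4, 14 shifted at least as many lists, the real one included. Some of the others keep most libraries of a group together and so carry part of the group difference, so this count decides nothing.

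By share of counts, antenna loci took 8.90% ± 1.20 in WT and 11.5% ± 1.12 in mEmBP-OE-4 (exact permutation p = 0.0571). Photosystem core loci took 5.82% ± 0.430 and 8.42% ± 0.765 (exact permutation p = 0.0286). Electron transport loci took 1.08% ± 0.123 and 1.93% ± 0.386 (exact permutation p = 0.0286). Calvin-Benson loci took 9.81% ± 0.419 and 10.7% ± 0.939 (exact permutation p = 0.114). In each of these 4 lists the share was higher in mEmBP-OE-4 in all 4 same-numbered pairs. For this a paired exact test gives p = 0.125, the smallest that 4 pairs allow. The same held for photorespiration, chlorophyll synthesis, secondary wall and nitrogen assimilation loci. The last took 0.502% ± 0.0136 in WT and 0.716% ± 0.0311 in mEmBP-OE-4 (exact permutation p = 0.0286). Shares of the senescence, abscisic acid and dehydration, defence, WRKY and cell division lists were lower in all 4 pairs. These values are mean ± SD with n = 4, and after Benjamini-Hochberg adjustment over the 17 lists the lowest exact p was 0.0607, so no list's share passed the threshold.

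**Figure D3:**
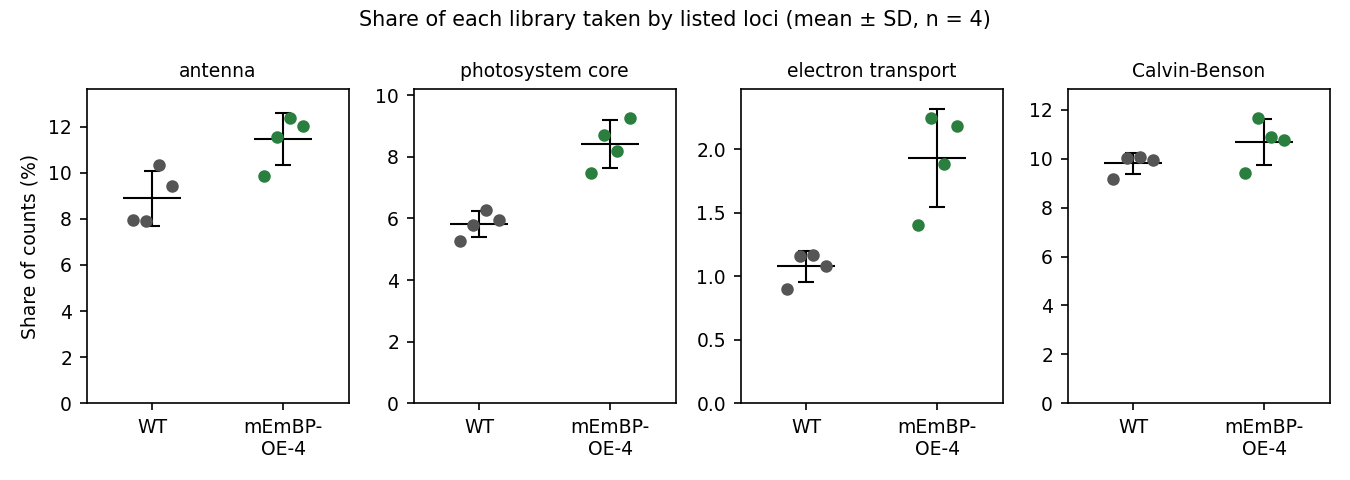
Percent of each library's counts taken by the loci of 4 photosynthesis lists, with a point per library and bars for mean ± SD (n = 4). Photosystem core and electron transport shares do not overlap between the groups, while antenna and Calvin-Benson shares do.

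None of the other testable lists passed camera. Of 7 nitrogen assimilation loci 4 rose by either adjustment (median 0.95), and of 6 sugar and starch loci 3 rose over all genes and 4 when adjusted over the list alone (median 0.62). Their adjusted p was 0.0681 and 0.0594 (camera with Benjamini-Hochberg adjustment), and the sugar and starch list passed with the replicate block (adjusted p = 0.0334, and 0.478 with the block and an estimated correlation). Of 6 senescence loci, covering chlorophyll breakdown and leaf ageing, 1 rose and 2 fell by either adjustment, with a median of -0.01 and a camera adjusted p of 0.616. With library totals alone 1 sugar and starch locus rose and 1 fell (median 0.16), no senescence locus rose and 4 fell (median -0.48), and the nitrogen assimilation median was 0.46. Os03g0327800, on the senescence list and on chromosome 3 by its ID, went from 40.1 ± 6.66 to 8.12 ± 1.67 CPM (SD, n = 4). Its log2 fold change was -2.30 (SE 0.17), with adjusted p = 2.68e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

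Of 13 circadian clock loci, 5 rose and 1 fell by either adjustment (median 0.46), but with library totals alone none rose, 6 fell and the median was -0.05, above the -0.47 of all genes. The number that rose was 1 without WT replicate 2 or mEmBP-OE-4 replicate 4 and 2 without WT replicate 1, 3 or 4 or mEmBP-OE-4 replicate 2. Of 10 flowering-time loci 4 rose by either adjustment (median 0.40), 2 without WT replicate 2 or mEmBP-OE-4 replicate 2 or 4, and with library totals alone 1 rose, 1 fell and the median was -0.09, likewise above that of all genes. Of 9 loci for abscisic acid and dehydration responses, 2 rose and 1 fell by either adjustment (median 0.79). Some of these loci averaged only 0.215 to 0.489 CPM in WT, so the median rests partly on loci near the floor. The lowest of them is among the 2 that rose, at 0.215 CPM in WT and 0.892 CPM in mEmBP-OE-4. The mean share of counts of the list was lower in mEmBP-OE-4, 0.00870% against 0.0106% in WT. The 2 that rose became 4 with the replicate block and 1 without WT replicate 3 or mEmBP-OE-4 replicate 2, and the locus that fell was not called without WT replicate 2 or 3. With library totals alone 1 rose, 2 fell and the median was 0.30. Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.191, 0.0669 and 0.191 for these 3 lists.

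Lists too small for a set test held a few large changes. Os05g0322900, the WRKY transcription factor locus, on chromosome 5 by its ID, went from 62.2 ± 22.2 to 4.94 ± 1.62 CPM (SD, n = 4), a log2 fold change of -3.65 (SE 0.35) with adjusted p = 1.02e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Os01g0750300, on chromosome 1 by its ID, was the only locus of the 3 on the secondary wall list that passed the filter and was tested. It went from 0.0832 ± 0.0371 to 5.34 ± 2.66 CPM (SD, n = 4), a log2 fold change of 5.97 (SE 0.53) with adjusted p = 6.67e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its WT libraries held 2 to 6 counts each, so the size of that change is imprecise. Of 3 defence loci 1 fell by either adjustment, and none without any of the WT replicates or without mEmBP-OE-4 replicate 2, 3 or 4. It became 2 with the replicate block and without mEmBP-OE-4 replicate 1. The cell division locus fell, by 0.75 on the log2 scale, but was not called without WT replicate 1, 2 or 3 or mEmBP-OE-4 replicate 4, and the locus for reproductive organs and seed was too low to test.

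The most abundant genes held larger mean shares of the counts in mEmBP-OE-4, but not past adjustment. The 200 most abundant genes held 55.1% ± 3.43 there and 46.2% ± 2.15 in WT (SD, n = 4, exact permutation p = 0.0286), and the 50 most abundant 37.9% ± 3.04 and 31.4% ± 2.15 (exact permutation p = 0.0571). TMM factors moved the other way, 0.853 ± 0.125 in mEmBP-OE-4 and 1.18 ± 0.0726 in WT (SD, n = 4, exact permutation p = 0.0286). After Benjamini-Hochberg adjustment over 10 library measures the lowest of these was 0.143.

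In locus order the densest window of 25 tested loci held 20 calls (permutation p = 0.26 over 1000 shuffles), while the longest unbroken run, 14 calls, was longer than most shuffles gave (permutation p = 0.028). Changes over 8-fold, looked at after the data were seen, were in part crowded. Up to 15 of 25 neighbouring loci carried one, where 0.756 is the mean over all windows and the highest of 1000 shuffles was 8 (permutation p = 0.001, the smallest they can give). Windows above the level that 95% of shuffles stayed within, 6, formed 5 segments on chromosomes 4, 7, 11 and 12, with 159 tested loci. Of these loci 67 changed over 8-fold (10.7% of all such changes), 57 lower and 10 higher in mEmBP-OE-4, and none of the 67 overlapped between the groups. Of all 8109 calls 7155 did not overlap either, and the 67 were picked as large calls, so this is not particular to the segments.

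**Figure D4:**
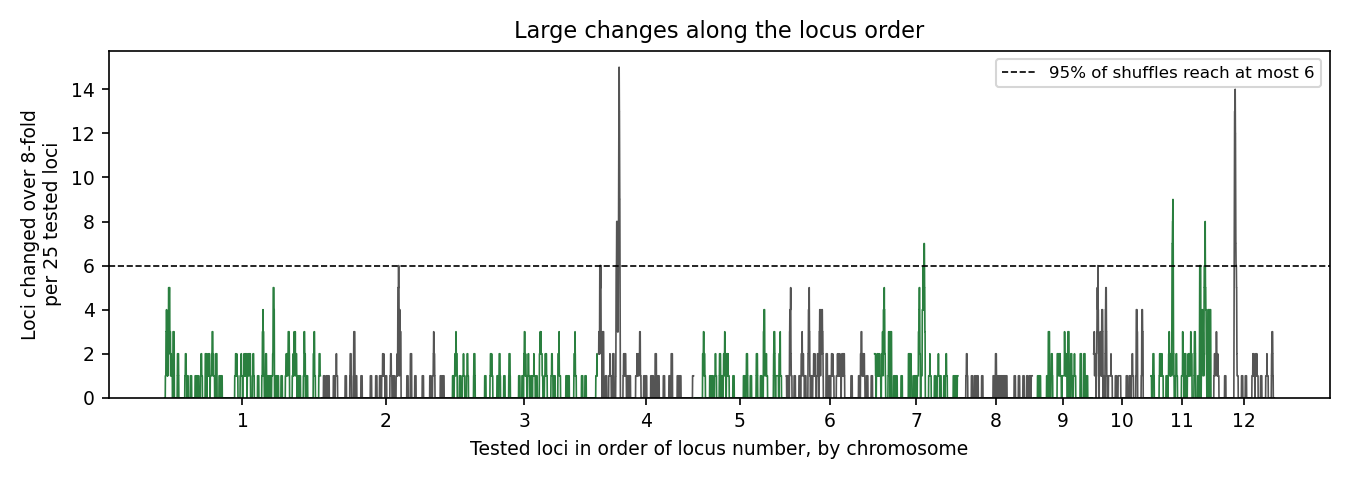
Number of loci changed over 8-fold in each window of 25 consecutive tested loci, ordered by locus number along the 12 chromosomes, with a dashed line at 6, the level that 95% of shuffles stayed within. The highest window, with 15, is on chromosome 4.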

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

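Of the tests below, those of scaling factors, of the hour of harvest and of library totals without the 50 most abundant genes were chosen after the result was seen. Among 52 groups of 4 values, Dixon's criterion picked out 7 in which a library stood far from the others, where chance gives about 1 in 20 groups. WT replicate 1 had 25883 genes detected against 24978 to 25102 in the other WT libraries. The same library had the lowest photorespiration share, 1.51% of counts, and the highest defence share of its group, 0.0167%. In mEmBP-OE-4, replicate 1 had the highest defence share, 0.0161%, and the lowest share for the pooled photosynthesis loci, 28.2% against 33.4% to 34.3%. WT replicate 2 had the lowest WRKY share, 0.00340%, and accordingly 29.0 CPM of Os05g0322900 against 72.1 to 75.6 in the other WT libraries. With both replicate 1 libraries left out, a setting chosen after the data were seen, 8603 genes changed and 43 of the 51 photosynthesis loci were higher.

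The rise of the photosynthesis loci was weighed against technical causes. Scaling factors that differed between the groups do not account for it as a whole, since with library totals alone the median of the 51 loci was 0.586, with 36 of them higher, although camera's calls of the 4 lists were lost there too with an estimated correlation (adjusted p = 0.109 to 0.171). A few abundant genes taking the counts were weighed only for the 19 loci outside the 50 most abundant genes. Those 50 held a larger mean share in mEmBP-OE-4, which on library totals lowers the other loci. Their removal could therefore only shift the 19 upward, so it is no test of this cause. The median of the 19 was 0.70 on library totals of all genes. On totals of the remaining genes it was 0.85, with 13 higher and 2 lower (1.20 under TMM, where the removal moved hardly any gene). Counts taken by the 50 would lower the 19 on library totals of all genes. Their median of 0.70 there argues against this cause for the 19. For the other loci, which are themselves among the 50 removed, the question stays open. A different hour of harvest cannot be told apart from the genotype, because 46.2% of 13 clock loci changed against 39.2% of all tested genes (Fisher's exact p = 0.59), which decides nothing. That mEmBP-1a raised these transcripts is therefore only a hypothesis that could fit the values. A single line, growth differences in the field and the hour of harvest are left open, as are the abundant genes for the loci among the 50.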

How the results depend on the processing

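The block and library totals with an estimated correlation, library totals without the 50 most abundant genes, the pooled photosynthesis loci, the removal of both replicate 1 libraries and the 8-fold windows were chosen after the data were seen. Of 823 values under alternatives 708 counted as unchanged, 18 lost and 16 gained a call, and 81 moved further. Direction was compared only for the 4 named loci and the list shifts, where none that was called changed it. Counts of genes and of list members had no direction to compare. Unchanged meant the same side of the threshold for calls and at most a 1.5-fold difference for counts. For shares of the most abundant genes it meant a difference within the SD. Medians of lists that camera did not call did change sign, clock (-0.05) and flowering (-0.09) with library totals alone and senescence, near 0, under several settings. Leaving out single libraries gave 6399 to 8450 changed genes and 36 to 45 photosynthesis loci higher. The replicate block, a paired fit, gave 10200 changed genes, 7359 at least 1.5-fold, and called sugar and starch (0.61, adjusted p = 0.478 by camera with an estimated correlation) but changed no other list call; besides the lists named in the report, 1 more locus each rose for electron transport, chlorophyll synthesis, sugar and starch, clock and flowering. Library totals alone gave 1752 higher and 8912 lower genes and called nitrogen assimilation (0.46, adjusted p = 0.169 by camera with an estimated correlation). At least 5 CPM in 4 libraries tested fewer genes and gave 5220 changed, 2602 higher, 2618 lower and 3316 at least 1.5-fold, and it called nitrogen assimilation (0.97). No filter called sugar and starch (0.71). Without the 50 most abundant genes, fewer list members were left, with 52 list calls in place of 83, 14 photosynthesis loci higher (13 on library totals) and 3 lists shifted in place of 6. Antenna, photosystem core and electron transport then had too few loci for camera and were not tested. Calvin-Benson, photorespiration and chlorophyll synthesis stayed called with the preset correlation. An estimated correlation left 0 lists (adjusted p = 0.356 by camera for those lost), at unchanged medians of 0.83 for antenna, 1.04 for photosystem core, 1.44 for electron transport, 1.16 for Calvin-Benson, 0.74 for photorespiration and 0.62 for chlorophyll synthesis. With the replicate block as well it left 0 lists (adjusted p = 0.478 to 0.489 by camera), at 0.81, 1.03, 1.38, 1.14, 0.70 and 0.60 in that order, and with library totals 0 lists (adjusted p = 0.109 to 0.171 by camera), at 0.33, 0.54, 0.92, 0.67, 0.23 and 0.12. Fry called 11 lists, adding senescence (-0.00698), nitrogen assimilation (0.95), sugar and starch (0.62), clock (0.46) and flowering (0.40), but it does not compare a list with other genes. Both replicate 1 libraries left out added nitrogen assimilation (1.03), sugar and starch (0.55) and flowering (0.41). Leaving out single libraries kept sugar and starch between 0.58 and 0.65, called without WT replicate 1 or mEmBP-OE-4 replicate 4, and flowering between 0.32 and 0.48, called without mEmBP-OE-4 replicate 1. Calls added by filters or by leaving out libraries rest on the preset correlation. The difference in share of the 10 most abundant genes was 2.39 percentage points in place of 6.57 for 50. Windows of changes over 8-fold reached 15, a call the windows of all changes did not give. Where no reason is given, the cause was not tested. No test of depth was run, and low loci such as Os01g0750300, with 2 to 6 counts in each WT library, have imprecise changes.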

Other observations

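Of the tests in this part, those of chance placement, of a single altered segment and of the matching of replicate numbers were chosen after the result was seen. All 35 splits of the 8 libraries into 4 and 4 were refitted without the replicate block, which excludes chance for the gene counts only if any split is as good as another. Only 1 split, the real one, reached 8109 changed genes and only 1 reached 6361 at least 1.5-fold, and the highest other split gave 0 for both. Every other split mixes WT with mEmBP-OE-4, so the difference between them widens its spread and lowers its count. The splits also cannot tell the genotype from any other difference between WT and mEmBP-OE-4 libraries. For the number of lists the splits decide nothing. At least 6 lists shifted in 14 of the 35 splits, the real one included, and the highest other shifted 10. Splits that keep most libraries of a group together still carry part of the difference between the groups, so they can shift the same lists. Chance is therefore neither excluded nor shown for the lists. Among the 8 splits that part all 4 same-numbered pairs, as the real one does, the highest other gave 0 genes and 10 lists, and 8 splits are too few for a share under 0.05.

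Of the changes over 8-fold, 10.7% lay in 5 crowded segments of the locus order, where most were lower in mEmBP-OE-4 (57 of 67), while over all loci more were higher (354) than lower (271). Chance placement is argued against by 1000 shuffles (permutation p = 0.001, the smallest they can give), and a single altered segment such as the insertion site by the 4 chromosomes involved. Segments that differ in sequence between the line and WT are a candidate explanation that stays open: 44.8% of large changes inside them were near zero in a group against 27.6% outside (Fisher's exact p = 0.00657), but the higher share was 14.9%, short of the balance set beforehand. Neighbouring genes raised or lowered together also stay open, since 75.8% of 62 pairs of successive large changes within a segment shared their direction where the split of directions alone gives 74.6%. A direct effect of mEmBP-1a on these segments was not tested.

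Libraries with the same replicate number deviated together, at correlations of 0.104 to 0.641 across genes. A shared field position, day or processing by replicate number may explain this, but 2 of the 24 matchings of the numbers, the real one included, had a mean correlation at least as high, so it cannot be told apart from chance likeness of a few libraries. The highest correlation was that of replicate 1. No biological explanation was tested.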
